A study of Rattus norvegicus with 72 samples.

How the data were processed

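RNA of rat medial collateral ligament was measured on 2-colour Agilent rat arrays, with a different sample in each channel. The table holds 72 samples: 5 of unmanipulated ligament, 5 severed and 5 sham on each of days 1, 2, 4, 10 and 14, 3 severed and 3 sham on day 7, 5 of cultured ligament fibroblasts at passages 3 to 7, and 6 of a reference RNA, 3 labelled Cy5 and 3 labelled Cy3. Per the labels, ligament samples come from separate animals, which the agreement of some columns described in the results leaves in doubt. A group counted as 1 sample has no spread of its own and takes that of the other groups. Nothing says that the fibroblast passages are independent cultures, so p-values that involve them measure a spread that may be technical.

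The values used are intensity values on a linear scale which, per the file headers, are the median feature intensity minus the local background at 635 or 532 nm, with no scaling between columns. Each array also carries a spot flag, a score that is 0 for a spot in use and negative for a flagged spot, per the file headers. The flags of the fibroblast columns were not used, because the column names do not give the passage, although the intensities of these columns were used as a group. No fibroblast spot was therefore treated as missing, against 21.4% to 56.9% of the spots of a column in unmanipulated ligament. For 3 samples the flags were taken from the other sample of the same array. A second table holds log2 values deposited by the authors, which follow log2 of the same intensity minus a constant per column, with column medians from 6.37 to 7.78. How that constant was chosen is not given in the sources used here, and the table served as an alternative. 8 columns of per-sample values were not used. The image software version is not given in the sources used here.

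The 44289 spots include 2917 control spots, which were left out, and 41372 spots of 41012 probes. Gene names are those of the array design, updated where an accession (8139 probes), a gene number (8738), a symbol (1410) or a synonym (423) matched the gene table; 22662 probes kept the name in the file. This gave 37763 gene entries, of which 15962 have a symbol. No genome was used here, so no coordinates are given.

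Intensities were quantile normalized across the 72 columns, set to a floor of 50 and put on the log2 scale, after which flagged spots were treated as missing. Spots of a probe were averaged, and the probe with the highest mean over the 61 ligament samples stood for its gene. A gene was tested where it reached 100 in at least 3 samples of a group and had at least 2 unflagged values in each group compared. Folds near the floor understate the change of dim genes. Column median intensities ran from 8 to 13062, and up to 84.9% of the spots of a column were flagged; the number of arrays limits the precision.

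A model with a mean per group and a dye term, which only the reference RNA identifies, was fitted with limma 3.58.1 in R 4.3.3 to all 72 samples (lmFit, then eBayes with trend = TRUE and robust = FALSE). Tests were two-sided with Benjamini-Hochberg adjustment at 0.05, and all adjusted p-values below come from limma. Samples that share an array were treated as independent in this fit. Dye and surgery split the samples of a day in the same way. The label field gives severed samples as Cy3 on days 1, 2 and 4 and as Cy5 on days 7, 10 and 14, so that by this field the dye cancels in the mean of the 6 days; by the header it does not. For day 2 the file header gives the opposite dyes, and the negative-control medians go with the header (-1 to 30 in severed, 13 to 171 in sham). Which entry is wrong cannot be told. If the label field is right the day 2 columns would be exchanged, and each day 2 direction of the header reading would turn. Neither reading is free of doubt. The fit takes the dyes of the label field with the day 2 columns as labelled, which matches neither reading in full. Both the header with these columns and the exchanged columns are therefore given beside it. The label field had been fixed as the source before the data were examined. It was set aside for the header during the work and then restored, after counts under both had been seen, because the fixed design names it.

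24 gene lists with 515 entries, of which 469 of 510 different genes are in the table, were fixed before the data were examined. They were tested with limma's camera on the moderated statistics (preset correlation 0.01), with an estimated correlation, and with fry. The estimated correlation was the mean pairwise residual correlation within groups, and fry needs complete values and used the flagged spots. Random lists matched in signal to the skeletal muscle list had a median correlation of 0.276. The estimate thus also holds shifts shared by many genes of a column, including those of columns that are doubted below. A list that does not hold with it is therefore not shown to be unchanged. Genes named in the text follow a rule fixed before the data were examined: the 6 largest rises and falls among genes past the threshold with and without the dye term and changed the same way throughout, up to 4 members of each list past the threshold (otherwise its 2 brightest), and, for severed against sham, a fixed set that includes collagens, matrix proteases, tendon markers and cytokines. Tnc and Scx of that set are not among the gene entries used here. A few genes that the rule names are not reported here.

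The fit was tested on simulated data with 200 changed genes. Each gene was drawn as its mean over all samples plus independent noise, with no dye difference and no correlation within an array. For the mean of 6 days the change was the same on every day. The simulation therefore does not test the dye term or the effect of shared arrays. For the mean of 6 days, 54 of 67 genes changed by 1 on the log2 scale and 67 of 67 changed by 2 were recovered. For single days, 1 to 11 of 67 changed by 2 were recovered, and 31 to 51 of 66 changed by 4. Severed day 14 against unmanipulated ligament recovered 38 of 67 genes changed by 2.

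Alternatives covered the dye term, the normalization, the floor, the filter, the probe rule, the second table, array weights, a fold of at least 2, the replicate number as a block and leaving out each sample in turn. Chosen after seeing the data were the file-header dye, the array (known from identical flags) as a block, leaving out the columns day 7 severed replicate 2 and day 4 severed replicate 4, leaving out day 10, day 2 or day 1 sham, counting the day 7 sham columns or the fibroblast columns as 1 sample, exchanging the day 2 or day 10 columns, the array as a random block (correlation 0.292 over 17383 genes), keeping flagged spots, subtracting negative controls, and variants of the choices that were themselves made after counts had been seen: the minimum of 2 values and the match of gene numbers.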

Results

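The medial collateral ligament, at the inner side of the knee, was severed in rats, and sham-operated animals had surgery that left it intact. Transcripts were measured at 1, 2, 4, 7, 10 and 14 days, beside unmanipulated ligament and fibroblasts cultured from the ligament. Median column intensity ran from 8 to 13062. Column day 7 severed replicate 2 had the highest median, 13062, and a median Spearman correlation of 0.081 with its own group. Column day 4 severed replicate 4 had a correlation of 0.0819 with its group.

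Some columns lay closer together than others. Over 4374 bright genes the 3 day 7 sham columns differed by a median of 0.0829 to 0.119 on the log2 scale, against 0.117 to 0.162 for the reference RNA in both channels of an array. The lowest value within the other ligament groups was 0.165. The 5 fibroblast columns differed by 0.111 to 0.287, with a median of 0.14 against 0.144 for that reference RNA. Unmanipulated replicates 1, 2, 3 and 5 differed from the day 1 sham replicates of the same number by 0.204, 0.165, 0.138 and 0.148, and replicate 4 by 0.368, while other numbers differed by 0.223 to 0.369. Of 120 ways to match the numbers 2 were as close (exact permutation p = 0.0167, one-sided). Columns are treated below as separate samples, as the labels have them. Results are also given with the day 7 sham or the fibroblast columns counted as 1 sample, without day 1 sham, and with the day 2 or day 10 columns exchanged. These were chosen after seeing the data.

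The first comparison asks what severing adds to the surgery over the whole course. Over the mean of 6 days, Comp, a matrix protein of tendon and cartilage, fell by 1.13 on the log2 scale (SE 0.213, n = 26 and 26, limma adjusted p = 0.00424), from 14.18 ± 1.09 (SD) in sham to 13.17 ± 1.25 in severed samples. Comp was not lower on every day: its mean was slightly higher in severed than in sham samples on days 2 and 10. Tnmd, the tenocyte membrane protein tenomodulin, fell by 1.04 (SE 0.255, n = 28 and 28, limma adjusted p = 0.039), but not on every day: it differed by -2.32, -1.02, -1.61 and -3.10 on days 1, 2, 4 and 7 and by 1.38 and 0.45 on days 10 and 14, none past the threshold. Ucma, a cartilage matrix protein, fell from 12.97 ± 1.31 (SD) in sham to 11.70 ± 1.86 in severed samples (SE of the difference 0.301, n = 26 and 26, limma adjusted p = 0.00886). On day 10, however, Ucma was higher in severed samples. Col11a2, a chain of a minor fibrillar collagen, fell by 0.70 (SE 0.175, limma adjusted p = 0.0425).

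In all, 38 of 8042 genes passed the threshold, 5 higher and 33 lower in severed ligament, and 27 of the 38 have a symbol. This count and the p-values above come from a fit that matches neither reading of the day 2 entries in full. With the file-header dye no gene passed, and both readings are given below. Sncg and Ddah2, an enzyme that degrades inhibitors of nitric oxide synthesis, had the same sign on all days, with changes of -0.69 and -0.60. Of 6 tested members of the tenocyte list, 2 fell and none rose (median -0.63, camera adjusted p = 0.000696; adjusted p = 0.168 with an estimated correlation). Of 12 members of the list of small leucine-rich proteoglycans and mature matrix, Comp fell (median -0.38, camera adjusted p = 0.00873; adjusted p = 0.588 with an estimated correlation). Of 7 erythrocyte genes, Epb42, a red cell membrane protein, fell by 0.55 (camera adjusted p = 0.00113 for the list; adjusted p = 0.168 with an estimated correlation). None of 14 cell cycle genes passed alone, while the list was shifted up (median 0.19, camera adjusted p = 0.00687; adjusted p = 0.546 with an estimated correlation). Adjusted over the list alone, 4 tenocyte genes, 4 of the mature matrix list and 4 erythrocyte genes were lower. Transcripts of matrix proteins of repair did not pass: Col1a1 differed by -0.14, Col3a1 by -0.03, Postn by -0.12, Mmp13 by -0.03 and Timp1 by 0.01. Dcn and Fmod differed by -0.73 and -0.68 with limma adjusted p of 0.236 and 0.146. Postn and Mmp13 ran opposite on day 10 to days 7 and 14, none past the threshold, so their small means hide differences of both signs.

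With the file-header dye no gene passed (limma; 431 at an unadjusted p under 0.05), with Comp at -1.11 (SE 0.296), Tnmd at -0.91 (SE 0.36) and Ucma at -1.49 (SE 0.418), while the 4 lists stayed past the threshold (highest camera adjusted p 0.0361). With the day 7 sham columns as 1 sample 4 genes passed, among them Comp (limma adjusted p = 0.0362), while Tnmd and Ucma had limma adjusted p of 0.164 and 0.0702. Without day 7 severed replicate 2 that of Tnmd was 0.0567. With the day 2 columns exchanged, the other reading of the 2 dye entries, 18 genes passed (1 up, 17 down), of which 6 are among the 38. Comp was then at -1.18 (limma adjusted p = 0.00318), Tnmd at -0.83 (0.13) and Ucma at -1.22 (0.0578). Epb42 was at -0.12, and of the 4 lists erythrocytes no longer passed, while tenocytes (median -0.49, camera adjusted p = 0.00141; adjusted p = 0.364 with an estimated correlation), mature matrix and cell cycle genes did (both 0.685 with an estimated correlation). With the day 10 columns exchanged 63 genes passed (9 up, 54 down), 20 of them among the 38, and 520 with the file-header dye. Comp, Tnmd and Ucma were then at -1.26, -1.50 and -2.40 (highest limma adjusted p 0.0254), while Epb42, Sncg, Ddah2 and Col11a2 no longer passed. The count was 145 without day 10, 2 without day 2, 147 with the array as a random block, 0 with the second table and 179 (32 up, 147 down) with the replicate number as a block. The split turned to 517 up and 133 down with array weights, to 87 up and 37 down without day 7 severed replicate 2, to 495 up and 89 down without the 2 doubted columns, and to 5 up and 0 down with 75th percentile scaling, which moved the median of all genes from -0.09 to 0.18.

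**Figure D1:**
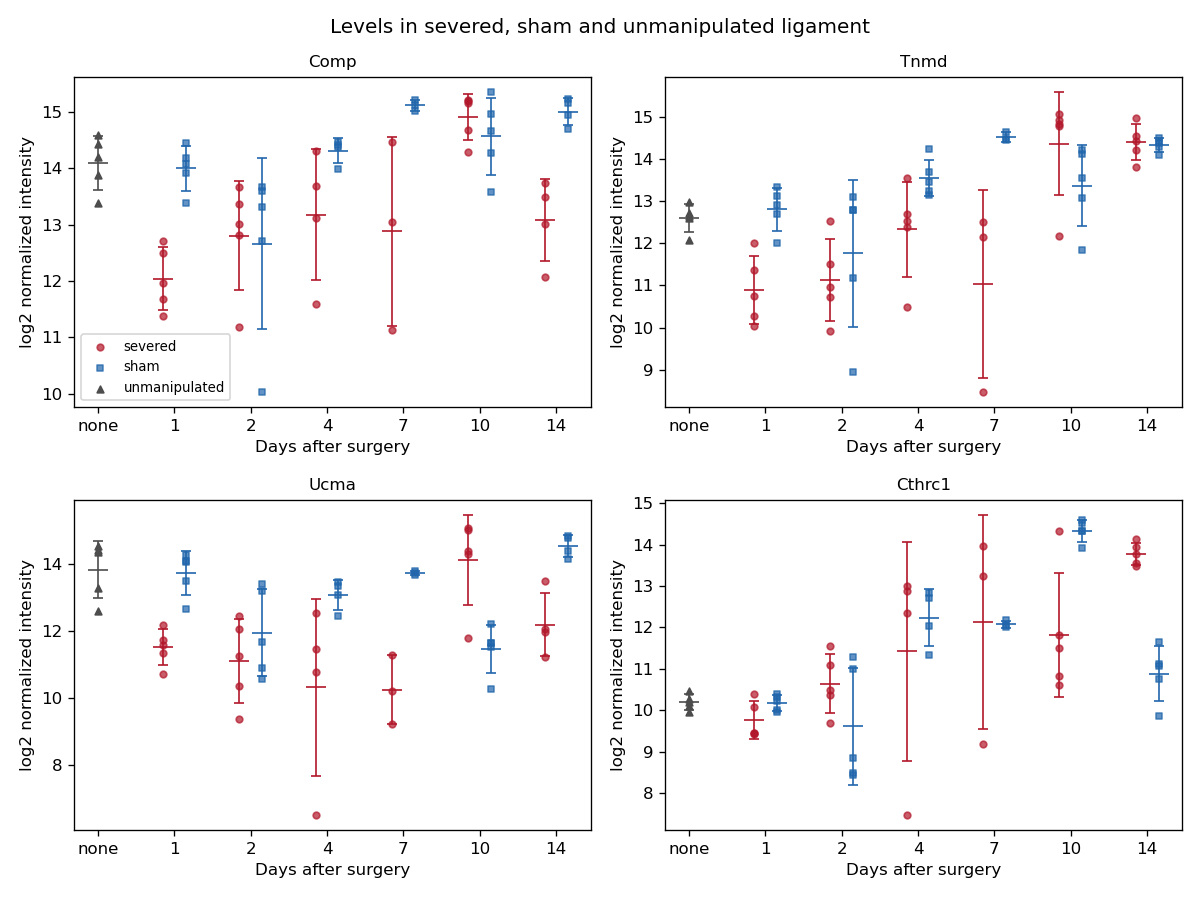
Log2 normalized intensity (y axis) of Comp, Tnmd, Ucma and Cthrc1, plotted because of values already seen, in each sample, by days after surgery (x axis; none is unmanipulated ligament), with points for samples, bars for the mean and SD, circles for severed, squares for sham and triangles for unmanipulated ligament. At day 10 the severed-minus-sham difference of Ucma is 2.69, against -3.47 at day 7 and -2.31 at day 14.

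Each day was then compared on its own. On day 1 the mature matrix list lay lower in severed ligament (19 genes, median -1.07, camera adjusted p = 2.37e-05; adjusted p = 0.1 with an estimated correlation) and neutrophil and acute inflammation genes lay higher (26 genes, median 0.57, camera adjusted p = 0.0045; adjusted p = 0.1 with an estimated correlation). Tnmd differed by -2.32 (SE 0.959) and Il1b, an inflammatory cytokine, by 0.74 (SE 0.565), neither past the threshold. Most day 1 sham columns lay close to the unmanipulated column of the same number, as given above. How far the day 1 values stand for severed against sham ligament is therefore in doubt. The mean of 6 days was not fitted without day 1. The lists of collagens (median -0.58, camera adjusted p = 0.0317), collagen processing (-0.56, 0.00477), tenocytes (-0.26, 0.0317) and TGF-beta and BMP signalling (-0.25, 0.0397) were also lower, with adjusted p of 0.52, 0.451, 0.221 and 0.323 with an estimated correlation. Severed samples were also set against same-dye sham samples of other days, so that time differs. Mature matrix (median -1.69), tenocytes (-1.38), collagens (-1.12) and growth factors (-0.875) were then lower and neutrophil genes (1.11) higher. With an estimated correlation these held (camera adjusted p 0.00169, 0.00169, 0.00823, 0.0104 and 0.0182), as by the file header (highest 0.0418). Collagen processing (0.103) and TGF-beta (0.268) did not hold.

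On day 2, 5 genes passed and all were lower in severed ligament, among them Clcn6, a chloride transporter, at -3.26 (SE 0.647, n = 2 and 2, limma adjusted p = 0.0336), and LOC298627 and 2 entries with a sequence identifier for a name. The last 3 fall outside the rule for named genes and were chosen after their values were seen. With the file-header dye 3 passed, and Clcn6 was at -3.01 with a limma adjusted p of 0.0794. Skeletal muscle genes lay higher on day 2 (median 1.41, camera adjusted p = 5.94e-06; adjusted p = 0.672 with an estimated correlation), as did collagens (median 0.56, camera adjusted p = 0.0341) and glycolysis genes (median 0.85, camera adjusted p = 0.024), each with adjusted p = 0.672 with an estimated correlation. With the file-header dye the muscle list was the 1 list past the threshold. Set against sham samples of other days with the same dye, the muscle list (median -0.63, camera adjusted p = 0.00341) and collagens (median -0.28, camera adjusted p = 0.00802) were lower, with adjusted p of 0.649 and 0.357 with an estimated correlation. Of 11 lists past the threshold in this setting none held with an estimated correlation (lowest adjusted p 0.0785). With the dyes of the file header these were at -0.23 and -0.18 and did not pass (camera adjusted p = 0.311 and 0.767). Exchanging the day 2 columns turns every direction found with the file-header dye. With this exchange 3 genes passed, all higher, and the muscle list was lower (median -1.59, camera adjusted p = 3.05e-07, and 0.965 with an estimated correlation). The angiogenic factor Vegfa differed by 1.98 (SE 0.716, limma adjusted p = 0.528).

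On day 7 the 8 erythrocyte genes lay lower in severed ligament (median -2.21, camera adjusted p = 6.16e-08; adjusted p = 0.00363 with an estimated correlation). The tenocyte list (median -1.02, camera adjusted p = 0.0344) and the immediate early genes (median -0.82, camera adjusted p = 0.00486) were lower too, with adjusted p of 0.543 and 0.651 with an estimated correlation. Tnmd differed by -3.10 (SE 1.08) and the collagenase Mmp13 by 2.21 (SE 1.21), neither past the threshold. The severed group holds replicate 2, whose Tnmd level was 8.47 against 12.15 and 12.51 in the other replicates. Without it Tnmd differed by -1.81, erythrocyte genes stayed lower (median -1.93, camera adjusted p = 3.62e-08), the tenocyte list (camera adjusted p = 0.0665) and immediate early genes (median 0.07, camera adjusted p = 0.932) no longer passed, and 5 lists were higher. These were collagens (median 0.50, camera adjusted p = 9.06e-05), proteases and inhibitors (0.11, 0.000113), provisional matrix (0.53, 0.000375), cell cycle (0.36, 0.00452) and endothelium (0.64, 0.0354), with adjusted p of 0.0831, 0.0831, 0.159, 0.228 and 0.159 with an estimated correlation. Adipocyte genes were lower (-0.57, 0.017; adjusted p = 0.159 with an estimated correlation), and the erythrocyte list held (0.00202).

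**Figure D2:**
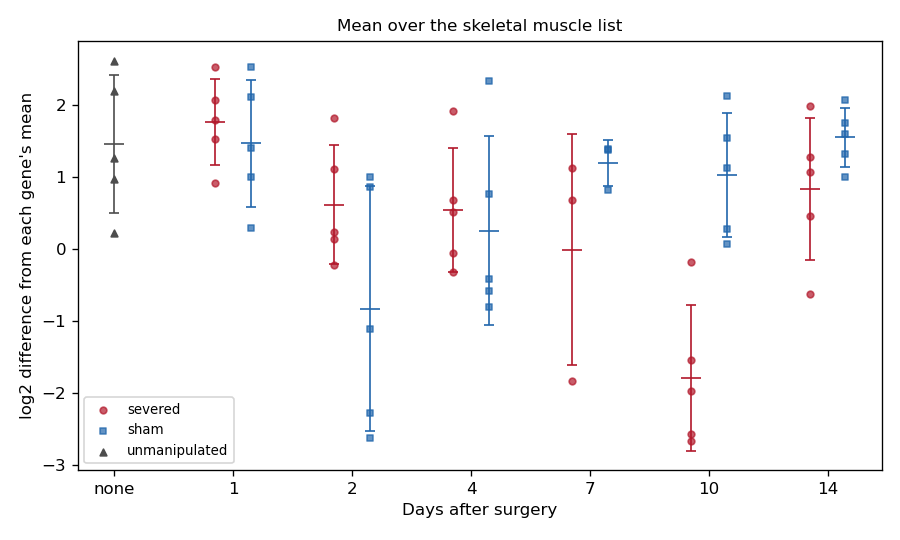
Mean of the skeletal muscle list in each sample on the log2 scale (y axis), by days after surgery (x axis; none is unmanipulated ligament), with points for samples, bars for the mean and SD, circles for severed, squares for sham and triangles for unmanipulated ligament. The severed samples of day 10 lie between -2.68 and -0.181 and the sham samples of day 10 between 0.066 and 2.13.

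Whether the severed and sham labels of day 10 are exchanged was left open. An exchange would turn each sign given here for severed against sham ligament of that day. It would not simply turn the values set against sham samples of other days, which would then come from other columns. On day 10, as labelled, the 23 skeletal muscle genes lay lower in severed ligament (median -2.58, camera adjusted p = 3.15e-24; adjusted p = 0.0589 with an estimated correlation). Collagens (median -0.79), provisional matrix glycoproteins (-0.66), proteases and inhibitors (-0.81), smooth muscle genes (-0.60) and glycolysis genes (-0.63) were lower, with camera adjusted p of 6.45e-07, 4.08e-05, 1.33e-08, 0.00107 and 0.0115, and adjusted p of 0.0644, 0.225, 0.0621, 0.0644 and 0.335 with an estimated correlation. Erythrocyte genes were higher (median 0.81, camera adjusted p = 0.00654; adjusted p = 0.217 with an estimated correlation). Set against sham samples of other days with the same dye, muscle genes stayed lower (median -2.02, camera adjusted p = 1.52e-19) and collagens were higher (median 0.54, camera adjusted p = 0.00206), as they were by the dyes of the file header (-2.56 and 0.28, camera adjusted p = 1.04e-32 and 0.0259). Provisional matrix, proteases, erythrocytes, smooth muscle and glycolysis then had medians of -0.06, -0.15, 0.28, -0.15 and -0.62 and did not pass, with camera adjusted p of 0.87, 0.663, 0.87, 0.31 and 0.106. Mature matrix (median 0.69), tenocytes (0.71), collagen processing (0.52), TGF-beta (0.49) and other growth factors (0.72) were higher, and macrophages (-0.54) and cell cycle genes (-0.33) lower (highest camera adjusted p 0.0242). By the file header macrophages (camera adjusted p = 0.126) and cell cycle genes (0.126) no longer passed, while glycolysis (0.0416) and Schwann cells (0.0419) did. With an estimated correlation none of the 9 same-dye lists held (lowest adjusted p 0.136, for muscle), and by the file header muscle alone (0.00996). Mmp13 differed by -3.70 (SE 1.02), Postn, a matricellular protein of repair tissue, by -2.68 (SE 0.952) and Spp1, osteopontin, by -2.43 (SE 1.2), none past the threshold. On day 14 Postn differed by 2.36 (SE 0.951), Mmp13 by 1.95 (SE 1.07) and Il1b by -1.41 (SE 0.592), none past the threshold, and no list passed on days 4 or 14. On day 4 Tnmd differed by -1.61 (SE 0.965).

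With limma no gene passed on days 1, 4, 7, 10 or 14, with 686, 434, 1323, 443 and 1035 genes at an unadjusted p under 0.05. With the array as a block 8 genes passed on day 14, 5 higher and 3 lower, and 2 on day 2. With the array as a random block, which also uses the samples without a partner, 47, 1, 3 and 35 passed on days 2, 7, 10 and 14; without the dye term 289 passed on day 2, 356 on day 7, 100 on day 10 and 355 on day 14.

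The change of the severing effect between days was tested next, with the dye cancelling. From day 7 to day 14 the severed-minus-sham difference of Tnmd rose by 3.54 (SE 0.962, limma adjusted p = 0.0288), that of Kera, the proteoglycan keratocan, by 3.13 (SE 0.799), that of Ccn2, a TGF-beta target, by 3.83 (SE 0.851) and that of the transcription factor Klf4 by 3.35 (SE 0.751). Hbb, a beta globin, rose by 3.77 (SE 1.01) and Bpgm, an enzyme of red cells, by 3.98 (SE 0.832). Rsad2 and Irf7, both interferon-induced, rose by 3.84 and 3.24. The growth factor genes Ptn, Igfbp6 and Igfbp5 rose by 3.10, 2.72 and 2.24, the protease Plau by 2.41, the macrophage gene Clec4a3 by 3.20 and the immediate early gene Ier3 by 2.74. Other leading rises were Rbm43, Or2t48 and Ptch1 (5.14, 4.67 and 3.88), and the leading falls were Psd4, Ubxn10, Pex11a, Bnc2, Zfp54 and Rab11fip3 (-5.52, -4.93, -4.37, -3.99, -3.97 and -3.70).

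Without day 7 severed replicate 2 none of these genes passed (lowest limma adjusted p 0.0883, for Plau), and Ubxn10 was not tested. Estimates over 1.5 times smaller were those of Tnmd (2.26), Ptch1 (2.25), Bpgm (2.53), Ccn2 (2.50), Klf4 (1.81), Hbb (1.94), Irf7 (1.56), Ptn (1.88), Igfbp6 (1.5), Clec4a3 (1.73), Ier3 (1.37) and Bnc2 (-1.77).

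Of 13567 genes, 537 passed (488 higher, 49 lower) while the median of all genes was 0.53, and no list passed (limma; the lowest camera adjusted p was 0.0643, for erythrocytes). With the day 7 sham columns as 1 sample 3 genes passed, and the limma adjusted p of Tnmd was 0.277. The count was 13 without day 7 severed replicate 2, 2125 and 2369 without day 7 severed replicates 1 and 3, 175 without day 7 sham replicate 2, 345 and 304 without day 14 severed replicates 2 and 4, 318 without day 14 sham replicate 2, 3 with flagged spots kept and 0 with the second table. From day 1 to day 4 no gene passed (limma; 875 at an unadjusted p under 0.05), with Lox, the collagen cross-linking enzyme, at 1.75 (SE 0.988), Mmp3 at 1.63 (SE 0.732) and Col3a1 at 0.84 (SE 0.351), and no list passed.

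Sham surgery was set against unmanipulated ligament over days 1, 2 and 4. Trpv6, an epithelial calcium channel, was higher in sham ligament by 2.92 (SE 0.586, n = 7 and 2, limma adjusted p = 0.0323). In all 10 of 9825 genes passed, 9 higher and 1 lower, and 3 of the 10 have a symbol. The 22 skeletal muscle genes lay lower (median -1.26, camera adjusted p = 1.09e-16; adjusted p = 0.255 with an estimated correlation), and cell cycle genes higher (median 0.41, camera adjusted p = 0.0487; adjusted p = 0.937 with an estimated correlation). With the file-header dye, which sets day 2 sham apart as Cy3, 3 genes passed; the count was 86 (61 up, 25 down) with 75th percentile scaling and 0 with at least 3 values per group, and the second table gave 1 up and 4 down. Without 1 sample the count lay between 1 and 11. Day 1 sham lay close to unmanipulated ligament, and without it 93 genes passed (69 up, 24 down; 9 with the file-header dye), with Trpv6 at 3.36 (SE 0.629) and the muscle list at -1.83 (camera adjusted p = 7.68e-19; adjusted p = 0.159 with an estimated correlation), while cell cycle genes, at a larger median of 0.57, did not pass (camera adjusted p = 0.0662). With the day 2 columns exchanged 2 genes passed, both higher, with Trpv6 at 2.24 (limma adjusted p = 0.358). The muscle list was then at -0.69 (camera adjusted p = 7.32e-08) and cell cycle genes at 0.40 (camera adjusted p = 0.00487), and erythrocyte genes were lower (-0.40, camera adjusted p = 0.0235), each with adjusted p = 0.634 with an estimated correlation.

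Severed ligament at day 14 was set against unmanipulated ligament, both in Cy5. Cthrc1, a secreted protein of repair tissue, rose by 3.58 (SE 0.696, n = 5 and 5, limma adjusted p = 0.00151), Fbn2, a microfibril protein, by 2.41 (SE 0.376), Col11a1 by 1.99 (SE 0.396) and Col5a2 by 1.57 (SE 0.336), while Spp1 fell by 2.54 (SE 0.693). Among mature matrix genes Ogn, Cilp and Bgn, biglycan, rose by 2.68, 1.70 and 1.30, and Prg4, the joint lubricant lubricin, fell by 2.07 (SE 0.501, limma adjusted p = 0.0143). Of vessel genes Kdr, a VEGF receptor, and Apln rose by 1.65 and 1.72, and the pericyte gene Rgs5 rose by 1.68. The neutrophil genes S100a9 and Il1b fell by 2.40 (SE 0.589) and 1.45 (SE 0.368), and Trem2, a macrophage receptor, and the protease Mmp12 rose by 1.26 and 1.88.

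Igf1, a growth factor, rose by 1.82 (SE 0.284, limma adjusted p = 2.9e-05) and Mdk by 1.39. Col10a1, Matn3 and Acp5, of cartilage and bone cells, rose by 2.78, 2.21 and 1.79, and RT1-Bb, a class II antigen gene, rose by 1.44. Among the largest rises were Plekhg2 at 5.61, Lrrc23 at 4.73, Or5as1 at 4.10 and Nppc, a natriuretic peptide, at 3.56. The largest falls were Csrp3, a muscle protein, at -3.29, the chaperone Hspb1 at -3.20, the metallothionein Mt1 at -3.01 (SE 0.414, limma adjusted p = 3.93e-06), Pla2g2a at -2.98, the acute phase gene Serpina3n at -2.87 and Psmd11 at -2.81; Lipe, a lipase of fat cells, fell by 1.99.

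In all 311 of 15053 genes passed, 232 higher and 79 lower. Of 17 collagens 2 rose, of 15 provisional matrix genes 2 rose and 1 fell, of 14 mature matrix genes 3 rose and 1 fell, and of 9 tenocyte genes none passed. Camera placed collagens (median 0.56), growth factors (0.83) and endothelium (0.63) higher and glycolysis (-0.43) and skeletal muscle (-0.58) lower, with adjusted p of 0.0321, 0.0208, 0.0321, 0.00217 and 0.00391, and adjusted p of 0.711, 0.542, 0.542, 0.542 and 0.713 with an estimated correlation. The second table turned the split to 19 up and 621 down, 75th percentile scaling gave 1670 and array weights 2005. Without unmanipulated ligament replicates 1 or 3 the count was 173 or 156, and without day 14 severed replicates 1, 2 or 4 it was 193, 167 or 193.

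Cultured fibroblasts were set against unmanipulated ligament, which asks how far cells in culture keep the transcripts of the tissue. Red cell and muscle genes were far lower in culture: Hbb-b1 by -8.57 (SE 0.4, n = 5 and 5, limma adjusted p = 1.97e-23), Myh1, a fast myosin, by -8.23 (SE 0.8) and Tnnc2 by -7.60 (SE 0.74). All 8 erythrocyte genes and all 23 skeletal muscle genes tested fell, with medians of -5.68 and -5.17. Ligament genes fell as well, with Dcn, decorin, at -6.96, Comp at -5.95, Tnmd at -5.67, Fmod at -5.25 and Thbs4 at -4.87. Of 12 tenocyte genes 5 fell, and of 19 mature matrix genes 10 fell and 2 rose.

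Genes of other cells of the tissue fell: 15 of 24 macrophage genes, with Lyz2, lysozyme, at -6.40 and Tyrobp at -5.29, 11 of 20 endothelial genes, with Emcn at -3.24 and Vwf at -2.83, 5 of 22 neutrophil genes, with Il1b at -5.76, 3 of 12 lymphocyte genes, with Cd3g at -2.30, 4 of 17 adipocyte genes, with Cfd at -6.07, and 11 of 20 antigen presentation genes, with Cd74 at -4.75. In the macrophage, neutrophil, adipocyte and antigen presentation lists 1 gene each rose. Of 33 cell cycle genes 6 rose, with Aurkb at 1.54 and Ccnb2 at 1.70. Of 19 collagen processing genes 4 rose, with Loxl3 at 2.60, and of 20 collagens 3 rose, with Col5a1 at 2.70 (adjusted p = 0.0939 and 0.35 for these lists with an estimated correlation). In the TGF-beta and BMP list 5 of 23 rose, with Id3 at 3.03 and Tgfb3 at 2.71, and 1 fell. Ptgr1, a prostaglandin-metabolizing reductase, rose by 4.67 and Emilin1 by 3.58. The growth factor Igf1 fell by 3.08.

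In all 3054 of 29383 genes passed, 940 higher and 2114 lower. With the fibroblast columns as 1 sample 509 passed (50 up, 459 down), a count whose spread comes only from the other groups and which says nothing of the variation between cultures. Emcn, Aurkb, Ccnb2, Loxl3 and Col5a1 then did not pass (limma adjusted p of 0.0763, 0.356, 0.687, 0.079 and 0.0722). Camera passed 17 of 24 lists, and 12 held with an estimated correlation, among them erythrocytes (adjusted p = 3.4e-10), macrophages (2.73e-06), tenocytes (3.2e-05), skeletal muscle (0.000793), TGF-beta (0.000979) and cell cycle (0.0192). Collagens, collagen processing, glycolysis, immediate early genes and adipocytes were lost, with adjusted p of 0.35, 0.0939, 0.381, 0.35 and 0.0557 with an estimated correlation; the collagen median was -0.01 and the mean 0.28. Mast cells (median -0.08), provisional matrix (-0.33), proteases (0.02), other growth factors (0.21), smooth muscle (0.59), cartilage and bone (-0.77) and Schwann cells (-0.10) did not pass, with camera adjusted p of 0.915, 0.981, 0.517, 0.517, 0.537, 0.169 and 0.961, and epidermal genes lay higher (median 0.83, camera adjusted p = 0.00937; adjusted p = 0.0346 with an estimated correlation). The second table turned the split to 2901 up and 923 down, 75th percentile scaling gave 2460 up and 3252 down, and array weights gave 9572. In the main fit flagged spots were left out for ligament but not for fibroblasts, while the second table leaves spots of both empty. Whether this adds to the excess of falls was not tested.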

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

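The tests of the dye, of single columns and of day 10 were chosen only after the results were seen, while those of low signal and of other splits of the samples were not. The check for a sample far from the rest of its group covered 35 groups for column measures and 130 for fixed genes, and marked 8 and 12; chance marks about 1 in 20 groups. The median intensity of day 4 severed replicate 4 was 186 against 59 for the nearest sample, that of day 10 severed replicate 5 was 220 against 34, and that of day 10 sham replicate 5 was 324 against 77. The last 2 share an array on which 2.24% of spots carry a flag, against 60.3% for the nearest. The median Spearman correlation with the own group was 0.0819 for day 4 severed replicate 4 (nearest 0.709), 0.667 for day 4 sham replicate 1 (nearest 0.8) and 0.466 for one fibroblast column (nearest 0.822). In that fibroblast column Col1a1 was at 11.19, Lox at 7.62, Mmp13 at 9.54, Fmod at 7.65 and Spp1 at 8.99 on the log2 scale, each apart from the other fibroblast columns. In another fibroblast column Col3a1 was at 15.18. In day 4 severed replicate 4 Col3a1 was at 15.26 and Timp1 at 11.94, in day 10 severed replicate 5 Tnmd was at 12.18, in unmanipulated ligament Fmod was at 14.83 in replicate 2 and Vegfa at 8.63 in replicate 5, and in day 14 sham replicate 4 Fmod was at 15.66.

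The severing effect differed between days 14 and 7 for 537 genes by the test of the difference itself. Without day 7 severed replicate 2, the column with a median intensity of 13062, the called genes' estimates had a median ratio of 0.594 to those with it; the median size went from 2.36 (SE 0.628) to 1.38 (SE 0.54), all 537 kept their sign and 13 genes passed. The called genes' median signal lies at percentile 69 of the genes tested, which argues against dim spots. Leaving out day 7 severed replicate 3 instead, which leaves as many samples, gave 2369 genes. The fall to 13 is therefore not a matter of sample number alone, and the count of 537 rests largely on replicate 2. How much of the sizes comes from this column cannot be told with 3 samples in the group. The rest and a biological difference between the days cannot be told apart either. Over 100 splits, 2 gave as many genes, the real one included, with 698 the highest of the others. These splits take the columns as separate samples, which is in doubt for day 7 sham. They were not corrected for dye and mix both dyes within a group, while each real group holds a single dye. Dye differences can then lower the counts of the other splits, so the splits do not decide on chance.

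Over the mean of 6 days 2 of 6 tenocyte genes and 1 of 12 mature matrix genes fell, lists with adjusted p of 0.168 and 0.588 with an estimated correlation, and no call passed with the file-header dye. Estimates with the file-header dye had a ratio of 0.782 to 1.19 (median 1.01) to those with the label-field dye. The median size went from 0.822 to 0.799 and the SE from 0.193 to 0.266. The choice of dye entry for day 2 thus changed the sizes little and raised the SE. Only day 2 of the 6 days differs between the entries, so only a large dye difference in the reference RNA could have lowered the ratio far. The ratio therefore does not decide whether dye adds to the sizes. Without the 2 doubted columns a share of 0.974 of the calls still passed, so these calls do not rest on them. Many more genes then passed, and most of those were higher, as given above. The number of calls and the excess of falls over rises therefore do depend on the 2 columns. Only 1 of 100 splits, the real one, reached 38 genes, with 37 the highest of the others. These splits take the columns as separate samples, which is in doubt for day 7 sham. They were not corrected for dye and mix both dyes within a group, while each real group holds a single dye. Dye differences can then widen the spread of the other splits and lower their counts, so the splits do not decide on chance. Exchanged day 2 columns (18 genes, 6 of the 38) and exchanged day 10 columns (63 genes, 20 of the 38) stay open, as does an effect of severing itself, for which no explanation was tested.

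At day 10 Ucma, Postn, Mmp13, Spp1 and Cthrc1 ran opposite to days 7 and 14, which was noticed from the plotted genes and then tested on the same data; severed replicate 5 (Ucma 11.78, Cthrc1 14.33) lay within the sham range of both. Exchanged severed and sham labels at day 10 may account for it. Across 25390 genes the difference, not corrected for dye, correlated at -0.14 with the mean of days 7 and 14 (-0.146 to -0.0647 without 1 sample of day 10). This lies between the bounds of -0.2 for and 0 against, so an exchange cannot be told apart from a true day 10 difference. With day 7 alone the correlation was -0.177 and with day 14 alone -0.0571. The doubted column, day 7 severed replicate 2, was not left out in this test. After the dye correction the correlation with the mean of days 7 and 14 was 0.0922 (0.0587 to 0.0988). That correction subtracts a shared reference term from all 3 days and by itself makes them go together, so it does not decide. Dye error would make the uncorrected differences of these days, which share their dyes, go together. The value below 0 argues against it, though with day 14 alone it was only -0.0571. The 15 pairs of days correlated between -0.177 and 0.14 before and between -0.319 and 0.152 after the correction, and samples were kept as labelled.

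For days 1, 4, 10 and 14 and for day 4 minus day 1 the real count was 0, which all 100 of 100 splits reach, so these splits decide nothing (highest others 14, 657, 576, 126 and 175). Of 100 splits, the real one included, 98 gave as many genes for day 2 (real 5, highest other 760) and 8 for sham against unmanipulated ligament (real 10, highest other 156), so chance is not excluded there. Day 7 has 10 splits, too few for a share under 0.05 (real 0, highest other 1043, 10 as large). Splits of single days mix the dyes and so carry less dye error, and some called several times more genes than the real one, which points to a structure of the samples that was not tested further. For severed day 14 against unmanipulated ligament 1 of 100, the real one, was as large (311, highest other 20). This argues against chance, with the columns taken as separate samples. For fibroblasts 1 of 100 was as large too (3054; highest other 928), but these splits take the passages as separate samples, which nothing in the labels says.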

How the results depend on the processing

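The settings with the file-header dye, the array as a block, the doubted columns or days, kept flags, subtracted negative controls, 3 values per group and unmatched gene numbers, and those on day 1 and day 7 sham, the fibroblast columns and exchanged day 2 or day 10 columns, were chosen after seeing the data; the cause of a change was not tested unless stated. Of 9125 values of named genes under the alternatives listed beforehand 8725 kept their side of the threshold, 352 lost and 47 gained the call. Pgk1 in fibroblasts turned to -0.94 with the mean of all probes. Of 3982 values under added alternatives 3668 kept their side, 287 lost and 26 gained the call. Mmp13 in the mean turned to 1.21 with the day 10 columns exchanged and the file-header dye (limma adjusted p = 0.0103). Direction was compared only where a gene passed in 1 or both fits, so uncalled genes whose sign turned count as kept. Day 2 genes with the day 2 columns exchanged are not among the added values, because each is the file-header value with its sign turned. Clcn6 was then at 3.01 (limma adjusted p = 0.0794). Up to 84.9% of the spots of a column were flagged, and 8042 of 37763 gene entries were tested for the mean of 6 days.

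Counts are given in the order of the settings. No dye term: 1, 289, 3, 356, 100 and 355 genes for days 1, 2, 4, 7, 10 and 14, and 5 lists for day 14. 75th percentile scaling: 5 for the mean of 6 days, 6, 32 and 15 for days 1, 2 and 14, 7 for day 4 minus day 1, 86 for sham, 1670 for severed day 14 and 5712 for fibroblasts against unmanipulated ligament. Quantile within each dye: 87 for the mean, 1, 42 and 8 for days 2, 7 and 14, 204 for severed day 14. Floor of 20: 10 for day 2, 1 for day 4 minus day 1. Floor of 200: 64 for the mean, 27 and 6 for days 2 and 14, 3 for sham, 502 for severed day 14. Second table: 0 for the mean, day 2 and day 14 minus day 7, 5 for sham, 640 for severed day 14. Array weights: 650 for the mean, 162, 8, 774, 840 and 518 for days 1, 4, 7, 10 and 14, 13 for day 4 minus day 1, 93, 2005 and 9572 for sham, severed day 14 and fibroblasts. A fold of at least 2 left 7 for the mean, and leaving out the fibroblasts 2 for day 2.

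The numbers were not taken to pair the samples in the main fit, since not every pair correlated above 0.1. Of 28 same-numbered pairs 21 did and 21 matched their own number best. Most pairs thus share variation that the main fit treats as independent, and the counts of the block settings below differ from its own. The lowest, -0.274, do not share an array, which 23 of the 28 do. Of 26 severed and sham pairs on one array 21 correlated above 0.1 (lowest 0.0225, median 0.218), so the array is given as a block too. On day 10 all 5 same-numbered pairs matched their own number (0.345 to 0.584), as a hint from the data. Replicate block: 179 for the mean, 2 and 5 for days 2 and 7, 1 for day 4 minus day 1, 5 for sham and 185 for severed day 14; without the dye term 179, then 1, 325, 4, 703, 167 and 574 for the days and 1 for day 4 minus day 1; with the file-header dye 0 for the mean, 2 and 5 for days 2 and 7 and 1 for day 4 minus day 1. Fibroblasts were not paired with unmanipulated ligament, because their column names do not give the passage. Array as a block: 2 for day 2 and 8 for day 14; with the file-header dye 0 and 8; with no dye term 15, 565, 2, 320 and 1066 for days 1, 2, 4, 10 and 14. Array as a random block: 147 for the mean, 47, 1, 3 and 35 for days 2, 7, 10 and 14, 10 for day 4 minus day 1 and 816 for day 14 minus day 7; with the file-header dye 0 for the mean, 30 for day 2, 4 for sham and the same 1, 3, 35, 10 and 816. Same-dye sham, which sets severed samples against sham samples of other days: 446, 526, 389, 2295, 210 and 273 genes, with 11, 11, 8, 6, 9 and 6 lists for the days, among them muscle genes and collagens turned to lower on day 2 and collagens to higher on day 10; by the file-header dye 275, 206, 240, 2176, 115 and 205, with 11, 4, 0, 2, 9 and 3 lists, and the day 2 muscle genes and collagens did not pass.

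File-header dye: 0 for the mean, 3 for day 2, 3 for sham and 1 list for day 2. Without the 2 doubted columns: 584 for the mean, 43 and 147 for days 2 and 14, 1 for day 4 minus day 1, 86 for day 14 minus day 7, 23 for sham, 1267 and 5294 for severed day 14 and fibroblasts; by the file-header dye 31 for day 2 and the same 147, 1, 86, 1267 and 5294. Flags kept: 0 for day 2, 3 for day 14 minus day 7, 183 and 1698 for severed day 14 and fibroblasts, and by the file-header dye also 0 for the mean and sham. At least 3 values per group: 0 for day 2, 15 for day 7, 945 for day 14 minus day 7, 0 for sham. Negative controls subtracted: 1 for day 2 and 1 for sham. Day 7 sham as 1 sample: 4 for the mean, 0 for day 7 and 3 for day 14 minus day 7, with means unchanged and fewer samples; by the file-header dye 0, 0 and 3. Day 2 columns exchanged: 18 for the mean, 3 for day 2 and 2 for sham. Day 10 columns exchanged: 63 for the mean, 520 with the file-header dye. Fibroblast columns as 1 sample: 509. Without day 1 sham: 93 for sham, 9 by the file-header dye. Without day 10 the mean gave 145 genes (156 by the file-header dye), without day 2 it gave 2. With an estimated correlation 0 lists passed for the mean, days 1, 2 and 10, sham and severed day 14, and 1 for day 7; with fry 1 for the mean and 0 for days 1, 2, 7 and 10, sham and severed day 14.

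75th percentile scaling moved the median of all genes from -0.01 to 0.40 for day 1, from 0.00 to 0.69 for day 2, from 0.05 to 0.63 for day 14, from 0.53 to 1.01 for day 14 minus day 7 and from -0.02 to -0.40 for sham. The second table moved it to -0.67 for sham, -0.69 for severed day 14 and 0.41 for fibroblasts.

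Leaving out each sample gave 17 to 161 for the mean, 0 to 15 for day 2, 0 to 134 for day 7, 0 to 3 for day 10, 0 to 4 for day 14, 0 to 0 for days 1 and 4, 0 to 1 for day 4 minus day 1, 13 to 2369 for day 14 minus day 7, 1 to 11 for sham, 156 to 303 for severed day 14 and 2501 to 2842 for fibroblasts. For the mean, 18 of 56 samples moved the count by over 1.5 times: 25 and 22 without day 1 severed replicates 1 and 4, 23 and 24 without day 1 sham replicates 2 and 4, 61 without day 2 sham replicate 3, 62 and 69 without day 4 severed replicates 2 and 4, and 19 without day 4 sham replicate 2. It was 100, 124 and 161 without day 7 severed replicates 1, 2 and 3, 17, 20 and 21 without day 7 sham replicates 1, 2 and 3, 60 and 25 without day 10 severed replicates 2 and 5, 23 without day 10 sham replicate 2 and 24 without day 14 sham replicate 1. Day 2 gave 3, 0, 0 and 9 without severed replicates 1, 3, 4 and 5, and 0, 0 and 15 without sham replicates 3, 4 and 5. Day 7 gave 40 and 134 without severed replicates 1 and 3, day 10 gave 3 without severed replicate 5, and day 14 gave 1 and 2 without severed replicates 3 and 5 and 4 without sham replicate 3 or 4. Day 4 minus day 1 gave 1 without day 4 severed replicate 3 or 4. Sham against unmanipulated ligament gave 3, 3 and 4 without unmanipulated replicates 1, 2 and 3, 6 without day 1 sham replicate 1 or 4, 2 without day 2 sham replicate 1, and 6, 1 and 5 without day 4 sham replicates 2, 3 and 5.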

Other observations

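Tests of skeletal muscle genes in this part were set before the result was seen for the range within groups and after it for the correlation. The mean over the skeletal muscle list varied among samples of one group, from -2.63 to 0.992 in day 2 sham, from -0.808 to 2.33 in day 4 sham, from -1.84 to 1.13 in day 7 severed and from -0.635 to 1.99 in day 14 severed ligament on the log2 scale. Day 7 severed stands among these only through replicate 2, the doubted column at -1.84, since the other replicates lie at 0.681 and 1.13. In 4 ligament groups this range was above the day 10 difference of 2.58, which goes with the explanation of muscle tissue in some samples, as a hypothesis. The 23 muscle genes moved together within groups with a mean correlation of 0.618, above the 0.393 that marks the top 5 percent of 1000 random lists of like signal. This argues against overall signal differences between columns as the only source. The random lists had a median of 0.276, with the doubted columns kept, so a contribution of such differences is not excluded. Myh1 and Tnnc2, both of fast muscle fibres, were at 15.39 and 15.24 in unmanipulated ligament and at 7.16 and 7.64 in cultured fibroblasts. None of the genes of this list stands in another list.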
